A study of Homo sapiens with 6 samples.

How the data were processed

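Poly(A) RNA was sequenced on an Illumina instrument from 6 libraries of a human cell line that the labels give as A549, a lung adenocarcinoma line. Cells had been kept for 24 h with a combined plant extract (F/B extract, 3 libraries) or with its vehicle, DMSO (3 libraries). The series title names the extract as one of Flos Sophorae Immaturus, the flower bud of the pagoda tree, and broccoli seed. Groups and replicate numbers were taken from the sample titles, and the columns of the table were tied to samples through the library names in the labels. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

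The authors deposited 1 table of 1099 genes with values for all 6 libraries and their own comparison. Its estimated counts per gene, deposited by the authors, were not whole for 31.8% to 35.9% of values per library and were rounded to whole numbers. The authors also deposited TPM values (transcript abundances scaled to a fixed total) per library, with a gene length in bases for each gene. Their comparison holds a fold change as a ratio, a log2 fold change, a p-value and an adjusted p-value per gene, per the file headers, and was made with DESeq2, per the name the authors gave the table. The genome build was GRCh38.p13, per the submitters' processing notes. The aligner, the counting program and the annotation release are not given in the sources used here.

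The table holds part of the transcriptome, and the genes in it were chosen on the comparison itself. The authors' p-values and adjusted p-values follow the Benjamini-Hochberg relation for 11289 tested genes (largest relative error 0.00345), and the 1099 genes are ranks 1 to 1099 of that list, or 9.74% of it. The largest deposited p-value was 0.00535 and the largest adjusted p-value 0.0549. Genes outside the table were not analysed here, so a gene that is missing from it either had a larger p-value or was not tested by the authors. The deposited log2 fold changes are vehicle over extract: the sign of the TPM ratio of extract over vehicle was the opposite of theirs in 1091 of 1099 genes. All directions below are extract over vehicle, and genes that the authors' table marks as up are those lower with extract.

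Sums over the listed genes are not sequencing depth. They ran from 3084338 to 4640117 estimated counts per library and made up 30.1% to 33.1% of the TPM total. Scaling by TMM over the listed genes had been planned, but it centres on genes that were all selected as changed. The libraries were instead scaled by the size factors that the authors' fold changes imply. These were found by minimising the difference between DESeq2 fold changes and the deposited ones, which left a median absolute log2 difference of 6.1e-05 and a largest of 0.00135. The size factors were 0.940, 1.23 and 1.05 for vehicle replicates 1 to 3 and 0.920, 0.959 and 0.935 for extract replicates 1 to 3. Normalised counts below are rounded estimated counts divided by these factors. TMM, DESeq2 size factors and plain sums over the listed genes, and the scale implied by the TPM values, were used as alternatives, the last one chosen after seeing the data.

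Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, limma 3.58.1) over the 6 libraries with no covariate. Benjamini-Hochberg adjustment was made over 11289 genes, which takes every unlisted gene to have a larger p-value, and the threshold was 0.05. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. edgeR's filter on low counts removed 0 genes. DESeq2 (version 1.42.0), limma-voom, 2 other filters, the replicate number as a block, and leaving out each library in turn were alternatives.

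Before the data were examined, 33 gene lists were fixed, together with the rule for named genes. That rule took the 12 highest and 12 lowest log2 fold changes among called genes with a symbol (clone, LOC and LINC names left out) and with no overlap between the groups, up to 4 members per list by p-value, and 18 genes of the cell cycle and of the epithelial to mesenchymal transition. Some genes that it picks are not reported here, and counts and tests of lists include them. The rule's minimum of 5 CPM (counts relative to the library total) was replaced by a mean of 5 TPM in either group, since library totals are not given in the sources used here. The 14 lists with at least 5 listed members were tested with limma's camera on log2 counts (prior count 2, preset correlation 0.01), which sets a list against the other listed genes, and again with an estimated correlation. fry, a test of whether a list's genes move on balance one way, was an alternative. The annotation terms in the table with 10 to 500 listed genes were tested in the same way. List members past the threshold were also counted with adjustment over the list alone. No listed gene had a deposited p-value above 0.00535, so nearly all listed members pass there, and these counts add no support. Chosen after seeing the data, a hypergeometric test asked whether a list has more listed members than expected, taking all its members to be among the 11289 tested genes. Its p-values were adjusted over the lists with a listed member. The test takes genes as independent and equally likely to reach a small p-value. Correlated genes break the first premise, and abundant genes, which reach a small p-value at smaller changes, break the second. The estimated correlation was 0.46 within cytosolic ribosomal proteins, 0.42 within interferon-stimulated genes and 0.41 within ribosome biogenesis. It was 0.35 within immediate early genes and 0.30 within autophagy and lysosome. The hypergeometric p-values of these lists therefore overstate the evidence.

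Gene positions are from GENCODE release 29 on GRCh38, matched by gene identifier for 1085 of 1099 genes. Estimated counts per gene and library ran from 27 to 115730, with medians from 1322 to 1890. Counts were simulated for the 1099 genes with the same spread between replicates (dispersion 0.00277) for every gene. The test called 80.0% of 80 genes changed 1.25-fold, 98.8% of 80 changed 1.5-fold and 100% of 40 changed 2-fold. Of 899 unchanged genes it called 0, and 6 with adjustment over the simulated genes alone. Real spread varies between genes, and the listed genes were selected on small p-values, so these figures may be too favourable. Reads that fit several near-identical genes can be split between them by a program that estimates counts. Values of ribosomal protein genes, FTH1, FTL, KRT6A, KRT6B, KRT81, LGALS7B, NPM1 and HSPE1, which have such copies or pseudogenes, are uncertain in that respect. Whether strand was used in counting is not given in the sources used here. All pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 4.59 to 15.3), and none was treated as a duplicate.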

Results

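RNA of 6 libraries of cells labelled A549 was compared after 24 h with F/B extract or with vehicle (DMSO), 3 libraries per group. The library names and the expression of MTAP, given below, put the label A549 in doubt. The series title places the comparison in a study of tumour growth, arrest at the G2/M boundary of the cell cycle, and the epithelial to mesenchymal transition (EMT). Values cover the 1099 genes of the authors' deposited table, the 9.74% of 11289 tested genes with the smallest p-values. Estimated counts over these genes summed to 3436544, 4640117 and 3885606 in vehicle replicates 1 to 3 and to 3178678, 3242561 and 3084338 in extract replicates 1 to 3.

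With extract, interferon-stimulated and lysosomal genes were higher, and genes of ribosomal proteins and of ribosome biogenesis were lower. As lists these were called by camera with a preset correlation but not with an estimated one (adjusted p from 0.447 to 0.572), and of the 23 and 18 ribosomal members called lower, 3 and 3 passed with TMM over the listed genes. Among genes with a mean of at least 5 TPM in either group, the strongest decreases were in SERPINB2, an inhibitor of plasminogen activators, in ID3, an inhibitor of basic helix-loop-helix transcription factors, and in the keratin KRT13. ID3 (ENSG00000117318, GRCh38 chromosome 1, 23557918 to 23559794) went from 676 ± 23.1 to 247 ± 40.7 normalised counts (mean ± SD, n = 3 each), a log2 fold change of -1.45 (SE 0.11, edgeR adjusted p = 0.000267). KRT13 (ENSG00000171401, chromosome 17, 41500981 to 41505705) went from 483 ± 48.7 to 185 ± 13.98, or -1.39 (SE 0.10, edgeR adjusted p = 0.000267), and SERPINB2 was at -1.49 (SE 0.18). The highest was OAS2 (ENSG00000111335, chromosome 12, 112978395 to 113011723), an interferon-induced oligoadenylate synthetase, which went from 548.99 ± 51.3 to 970 ± 50.7, a log2 fold change of 0.82 (SE 0.08, edgeR adjusted p = 0.00120).

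By the rule for named genes, the others with the lowest log2 fold changes were CYP1A1 at -1.33, KRT81 at -1.24, LGALS7B at -1.20, CCNB3 at -1.12, POU2F3 at -0.94, CXCL8 at -0.93, GCNT3 at -0.92 and S100A4 at -0.90, and S100A2 was 1.99-fold lower. CYP1A1, an enzyme induced through the aryl hydrocarbon receptor (AhR), went from 345 ± 46.4 to 138 ± 11.7 normalised counts (SD, n = 3 each). CXCL8, the chemokine interleukin-8, went from 669 ± 1.61 to 352 ± 79.2. Those with the highest, after OAS2, were TMEM144 at 0.79, MAP2K6 at 0.76, CMPK2 at 0.74, SQSTM1 at 0.72, LCN2 and AMACR at 0.71, IFI44L at 0.68, VIM at 0.67, IFIT3 at 0.65, CROCC at 0.62 and IFI44 at 0.61. Of these 24 genes, 5 of the 12 highest and 10 of the 12 lowest kept their call in each of the 16 other settings. Some of these settings could not lose a call. The 2 other filters removed no gene, and adjustment over the listed genes alone called every gene. The calls of MAP2K6, CMPK2, LCN2, IFI44L, VIM, CROCC, IFI44, LGALS7B and POU2F3 were lost when vehicle replicate 2 was left out.

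**Figure D1:**
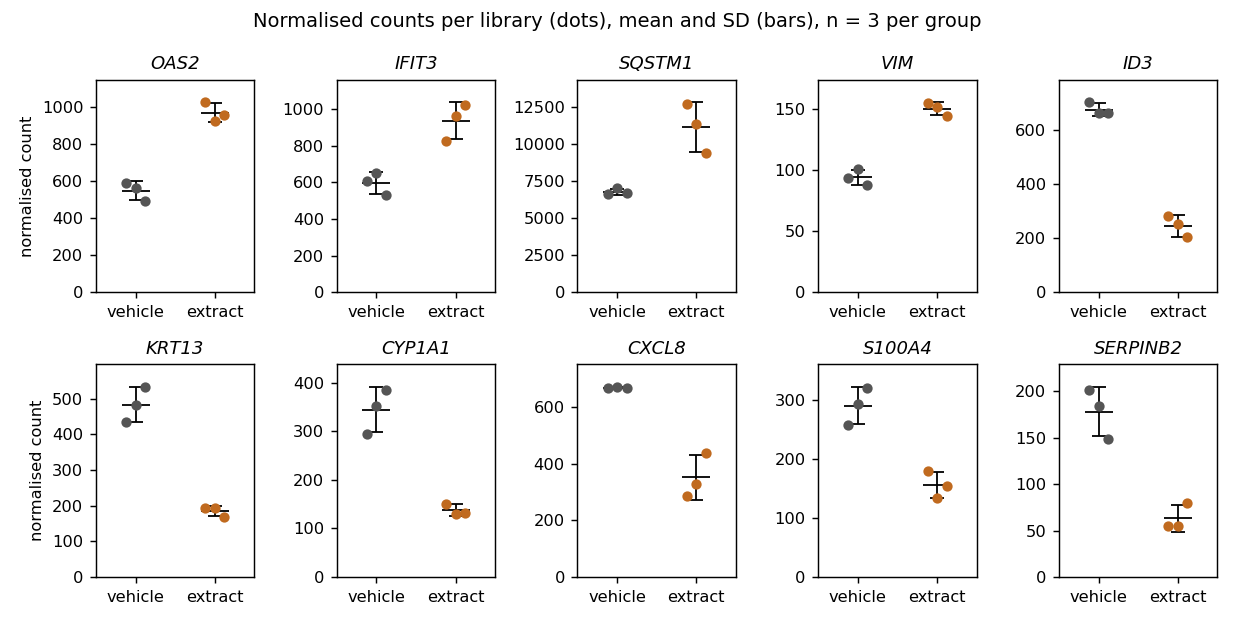
Normalised counts (y axis, estimated counts divided by the size factors, starting at 0) of 10 genes in the 3 vehicle and 3 extract libraries. Dots are libraries, horizontal marks are means and bars are SD. ID3 lay at 676 ± 23.1 in vehicle and 247 ± 40.7 in extract, and in all 10 genes the groups do not overlap.

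In all, 318 genes were called higher and 580 lower with extract by edgeR's quasi-likelihood test, so that 64.6% of calls were lower. The spread between libraries was estimated from the listed genes alone. These had been selected on small p-values in the same libraries, so the p-values may be too small. Changes were small: the median absolute log2 fold change in the authors' deposited table was 0.29, which is 1.22-fold. By the same table, 21 genes were more than 1.5-fold higher and 68 more than 1.5-fold lower. With an absolute log2 fold change of at least 1, edgeR called 0 genes higher and 11 lower. The groups did not overlap in 380 genes higher and 701 lower with extract, where 10% of genes would do so by chance among genes not chosen on the comparison. The split of calls depended on the scale: 371 higher and 197 lower (34.7% lower) on the scale implied by the TPM values, 386 and 126 (24.6%) with sums over the listed genes, 385 and 87 (18.4%) with TMM and 387 and 86 (18.2%) with DESeq2 size factors over the listed genes. These scales raise the median of all log2 fold changes by 0.09, 0.14, 0.15 and 0.17. Without vehicle replicate 2 the calls were 50 higher and 128 lower, without vehicle replicate 3 they were 80 and 224, and without extract replicate 2 they were 71 and 184.

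**Figure D2:**
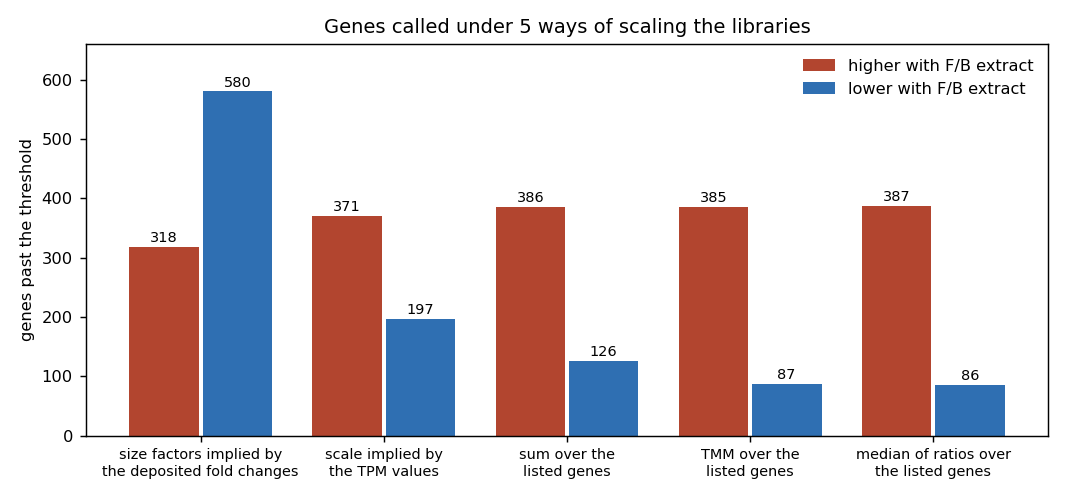
Number of genes past the adjusted p threshold (y axis) higher (red) and lower (blue) with F/B extract under 5 ways of scaling the 6 libraries (x axis). Genes called higher ran from 318 to 387, and genes called lower from 86 to 580.

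Interferon-stimulated genes, which carry the antiviral response, rose. Of 35 list members 19 were in the table, where 3.41 were expected (hypergeometric adjusted p = 4.61e-10). All 19 were higher with extract under the size factors used and under the 4 other scales, and 17 passed the test, or 19 adjusted over the list alone. The 17 fell to 7 without vehicle replicate 2, 8 without vehicle replicate 3, 8 without extract replicate 2 and 9 with the replicate number as a block. All 19 stayed higher, but no listed gene changed sign in these settings. The 4 other scales raise log2 fold changes, so the kept direction adds no support. The 17 included OAS2, the helicase sensors IFIH1 at 0.48 (SE 0.05, edgeR adjusted p = 0.00192) and DDX58 (RIG-I) at 0.40, IFIT3, MX2 at 0.52 and the signalling factor STAT2 at 0.47. The median was 0.42, and camera set the list above the other listed genes (adjusted p = 1.27e-07), a call lost with an estimated correlation (adjusted p = 0.447). IFIT5 at 0.27 and IRF9 at 0.20 missed the threshold and passed on the 4 other scales.

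Genes of autophagy and the lysosome rose as well: 10 of 32 members were in the table (3.12 expected, hypergeometric adjusted p = 0.00481), and all 10 were higher and passed, under all 5 scales and also adjusted over the list alone. Without vehicle replicate 2, vehicle replicate 3 or extract replicate 2, 3, 4 and 3 of them passed, and 5 with the block. All 10 stayed higher, but no listed gene changed sign in these settings. The 4 other scales raise log2 fold changes, so the kept direction adds no support. SQSTM1, the autophagy receptor p62, went from 6753 ± 218 to 11115 ± 1656 normalised counts (SD, n = 3 each), a log2 fold change of 0.72 (SE 0.09, edgeR adjusted p = 0.00320). The lysosomal enzyme CTSA was at 0.35, and the autophagy kinase ULK1 was at 0.25. The list median was 0.28 and the camera adjusted p was 0.000220, against 0.447 as adjusted p with an estimated correlation.

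Of 36 targets of NRF2, the regulator of the antioxidant response, 9 were in the table (3.50 expected, hypergeometric adjusted p = 0.0318), 7 higher and 2 lower, all past the test and all 9 adjusted over the list alone. HMOX1, which degrades haem, was at 0.59 (SE 0.14, edgeR adjusted p = 0.0282), SRXN1 at 0.37, the ferritin genes FTL and FTH1 at 0.32 and 0.29, NQO1 at 0.21 and the cystine transporter SLC7A11 at 0.20. SQSTM1 also belongs to this list. Of the 7 higher genes 2 passed without vehicle replicate 2, 3 without vehicle replicate 3, 2 without extract replicate 2 and 3 with the block. NFE2L2, the gene of NRF2 itself, was at -0.16 and TXN at -0.21. Under the 4 other scales neither of them passed, and NFE2L2 stood at 0.01 with DESeq2 size factors over the listed genes. The camera adjusted p was 0.0225, and 0.447 as adjusted p with an estimated correlation.

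Ribosomal genes fell. Of 44 cytosolic ribosomal protein genes 26 were in the table (4.28 expected, hypergeometric adjusted p = 2.08e-14), all 26 lower, 23 past the test and 26 adjusted over the list alone. RPL27 was at -0.55 (SE 0.06, edgeR adjusted p = 0.00142), RPS23 at -0.45 and RPL35 at -0.39. Of 30 ribosome biogenesis genes 20 were in the table (2.92 expected, hypergeometric adjusted p = 8.66e-13), all 20 lower, 18 past the test and 20 adjusted over the list alone. Both hypergeometric p-values take genes as independent, while the estimated correlation within the lists was 0.46 and 0.41. The nucleolar proteins NOP16, LYAR and GNL3 were at -0.52, -0.45 and -0.44, and NCL and NPM1 at -0.23 and -0.22. Medians were -0.26 and -0.32, and camera gave an adjusted p of 0.00681 for each, with 0.572 and 0.548 as adjusted p with an estimated correlation. The number of members called lower was sensitive to the scale, at 7 and 10 on the TPM scale and 3 and 3 with TMM over the listed genes. It was 3 and 5 without vehicle replicate 2, 9 and 7 without vehicle replicate 3, 3 and 6 without extract replicate 2, and 8 and 8 with the block. Of the ribosomal protein genes, 2 turned higher with TMM and 5 with DESeq2 size factors over the listed genes.

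**Figure D3:**
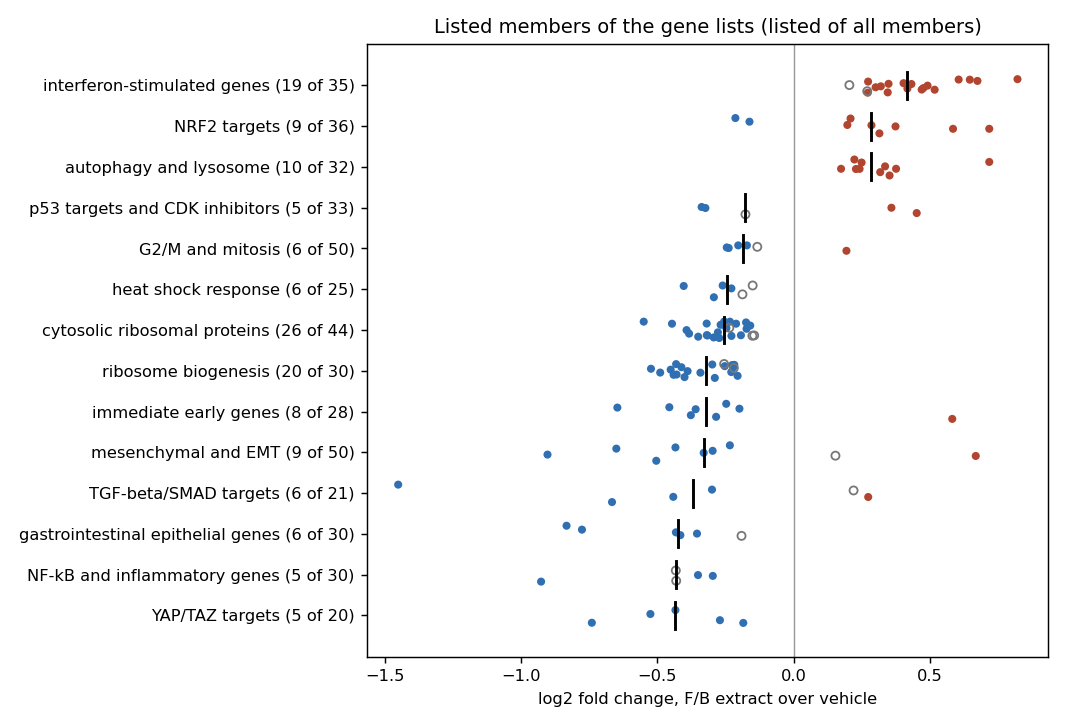
Log2 fold change, extract over vehicle (x axis), of each listed member of the 14 gene lists with at least 5 members in the table (y axis). Filled dots passed the edgeR threshold (red higher, blue lower), open dots did not, and vertical marks are medians. All 19 interferon-stimulated genes lie above 0, and all 26 ribosomal protein genes lie below 0.

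Genes of G2/M and mitosis were not over-represented. Of 50 members 6 were in the table, where 4.87 were expected (hypergeometric adjusted p = 0.633), and the camera adjusted p was 0.544. CENPF, a kinetochore protein, was higher at 0.19 (edgeR adjusted p = 0.0300). MAD2L1 at -0.25, UBE2C at -0.24, PRC1 at -0.20 and ECT2 at -0.17 passed, ANLN at -0.13 did not, and 5 of the 6 passed adjusted over the list alone. None of the 4 passed on any other scale, without vehicle replicate 2, without extract replicate 2 or with the block, and the call of CENPF was lost in these last 3 settings and without vehicle replicate 3 or extract replicate 3. The number of the 6 genes that were higher was 1, 2, 2 and 3 on the TPM scale, with sums, with TMM and with DESeq2 size factors over the listed genes. CDK1, CCNB1, CCNB2, CDC25C, PLK1, WEE1, CDKN1A and GADD45A were not among the listed genes. Of 43 genes of G1/S and DNA replication 3 were listed, among them UHRF1 at -0.25 and CDC6 at -0.34, and of 33 p53 targets and CDK inhibitors 5 were listed, among them CCNG2 at 0.45 and PLK2 at -0.34 (camera adjusted p = 0.699). Adjusted over the list alone, 3 and 4 of these passed. The 2 genes called lower in the G1/S list fell to 1 on the TPM scale and to 0 with sums, TMM or DESeq2 size factors over the listed genes. In the p53 list the 2 called lower fell to 1, 1, 1 and 0 on these scales. The 1 and 2 genes called higher in the 2 lists passed on all 4.

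Of 50 mesenchymal and EMT genes 9 were in the table (4.87 expected, hypergeometric adjusted p = 0.136), 2 higher and 7 lower under all 5 scales. The 4 other scales raise log2 fold changes by at most 0.17, less than any of the 7 decreases, so no sign could change. S100A4 at -0.90, the actin-binding TAGLN at -0.65 (SE 0.05, edgeR adjusted p = 0.000267), the collagenase MMP1 at -0.50, CCN1 at -0.43, COL1A1 at -0.33, FSTL3 at -0.30 and TPM1 at -0.23 fell. VIM (ENSG00000026025, chromosome 10, 17228259 to 17237593), the intermediate filament protein vimentin, rose from 94.0 ± 6.27 to 150.0 ± 5.11 normalised counts (SD, n = 3 each), a log2 fold change of 0.67 (SE 0.12, edgeR adjusted p = 0.0110). MMP14 at 0.15 missed the threshold and passed on the 4 other scales, while the call of VIM was lost without vehicle replicate 2, vehicle replicate 3 or extract replicate 2. All 9 passed adjusted over the list alone, and the camera adjusted p was 0.414. On each of the 4 other scales 3 of the 7 lower genes passed, as did 3 without vehicle replicate 2, 3 without vehicle replicate 3, 4 without extract replicate 2 and 4 with the block. CDH1, CDH2, FN1, SNAI1, SNAI2, ZEB1, TWIST1, MMP2 and MMP9 were not among the listed genes. Of 40 epithelial genes 3 were listed, with the junction protein CGN at -0.30 and the protease ST14 and its inhibitor SPINT1 at 0.23, both of which missed the threshold (edgeR adjusted p = 0.117 and 0.106) and passed on the 4 other scales. CGN passed on the TPM scale and on none of the other 3.

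Several signalling lists had members that fell. Of 28 immediate early genes 8 were listed (2.73 expected, hypergeometric adjusted p = 0.0249), 7 lower and 1 higher. DUSP1 was at -0.65, KLF4 at -0.46, DUSP4 at -0.38, MYC at -0.36 and KLF2 at 0.58. Of 21 TGF-beta/SMAD targets 6 were listed, with ID3, ID1 at -0.67, ID2 at -0.44 and SMAD7 at -0.30 lower, LTBP3 at 0.27 higher, and SKIL at 0.22 not past the test. All 5 listed of 20 YAP/TAZ targets were lower and passed, with ANKRD1 at -0.74 (SE 0.09, edgeR adjusted p = 0.00264) and F3, tissue factor, at -0.53. All 5 listed of 30 NF-kB and inflammatory genes were lower and 3 passed, CXCL8, NFKB2 at -0.35 and IER3 at -0.30. All 6 listed of 25 heat shock genes were lower and 4 passed, with HSPE1 at -0.40, though 1 turned higher with TMM and with DESeq2 size factors over the listed genes. Adjusted over the list alone, all listed members of these 5 lists passed, as nearly any listed gene would after selection on small p-values. The camera adjusted p was 0.195, 0.651, 0.169, 0.178 and 0.172 for these lists in turn. The last 4 lists were not over-represented past the threshold, with 2.04, 1.95, 2.92 and 2.43 members expected and hypergeometric adjusted p of 0.0543, 0.117, 0.374 and 0.0986. Of the lower members of the 5 lists, 7, 4, 5, 3 and 4 passed with the size factors used. On the TPM scale 4, 3, 2, 1 and 1 passed, and with TMM over the listed genes 2, 2, 2, 1 and 1. Without vehicle replicate 2 these numbers were 3, 2, 2, 2 and 2, without vehicle replicate 3 they were 3, 2, 2, 2 and 1, without extract replicate 2 they were 3, 2, 3, 2 and 1, and with the block 3, 3, 3, 2 and 1. Of 12 AhR targets 4 were listed, with CYP1A1, TIPARP (-0.34) and NFE2L2 lower and NQO1 higher. Of the 3 lower ones only CYP1A1 passed on the other scales.

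Lists with few listed members were ATF4 and the integrated stress response (3 of 36, CEBPB at 0.42), ER chaperones (2 of 26, MANF at -0.32) and metallothioneins (1 of 10, MT2A at 0.49). The same held for apoptosis regulators (4 of 32, BMF at 0.46 and CYCS at -0.41), cholesterol biosynthesis (2 of 25, INSIG1 at 0.58), glycolysis and hypoxia (3 of 32, PFKFB3 at -0.42 and HK2 at -0.33) and oxidative phosphorylation (3 of 37, NDUFA4 at -0.35). It also held for double-strand break repair (2 of 30, NBN at 0.24 and RPA2 at -0.34) and for phase II metabolism (2 of 24, GSTM4 at -0.30 and GSTM3 at -0.25). No tubulin, replication-dependent histone or leukocyte gene was listed, and 1 of 15 fibroblast and endothelial genes was (COL1A1). Of the lower genes given here with a value, only CYCS passed with TMM or DESeq2 size factors over the listed genes, and MANF and GSTM3 did not pass on the TPM scale either.

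The lists on cell identity bear on the labels. MTAP, which lies in a region that A549 is known to have lost, was at 48.9 to 60.5 TPM over the 6 libraries, and its log2 fold change was -0.19. Of 30 gastrointestinal epithelial genes 6 were listed, all lower with extract under all 5 scales, 5 past the test and 6 adjusted over the list alone (camera adjusted p = 0.148). The other scales move genes by at most 0.17, less than any of these decreases, so no sign could change. The 5 fell to 4 on the TPM scale, 3 on each of the other scales, 1 without vehicle replicate 2 and 3 without vehicle replicate 3 or with the block. VIL1, the brush border protein villin, was at 142 to 214 TPM and fell by 0.42 on the log2 scale (SE 0.04, edgeR adjusted p = 0.00135). TSPAN8 was at 182 to 229 TPM, TFF1, a gastric mucosal peptide, at 33.3 to 81.5, CDH17 at 33.6 to 48.0, EPS8L3 at 33.5 to 45.1 and REG4 at 5.83 to 11.6. VIM was at 4.32 to 12.2 TPM, below the median of the listed genes, which was 51.3 TPM in the library where it was lowest. Of 20 genes known to be abundant in A549 3 were listed (NQO1, SLC7A11 and LCN2), all higher and past the test under all 5 scales. The 4 other scales raise log2 fold changes, so the direction could not change there. Of the 3 genes, 0 passed without vehicle replicate 2 or vehicle replicate 3 and 1 without extract replicate 2 or with the block. Of 18 lung epithelial genes 1 was listed (LAMP3 at 0.35). The library names in the labels of all 6 samples begin with AGS, which is also the name of a gastric adenocarcinoma line.

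Among 320 annotation terms of the table, camera called 13 higher and 14 lower with extract, and 0 with an estimated correlation, where the adjusted p of the 10 terms named here was at least 0.744. The higher terms with the smallest p were the KEGG lysosome pathway (23 of 24 genes higher, adjusted p = 4.49e-06), the lysosome (28 of 31), defense response to virus (22 of 25), the lysosomal lumen (18 of 19) and innate immune response (22 of 29). The lower ones were structural constituent of ribosome (70 of 70 genes lower, adjusted p = 8.33e-05), the KEGG ribosome pathway (61 of 61), translation (65 of 66), cotranslational targeting through the signal recognition particle (52 of 52) and viral transcription (51 of 51), which share ribosomal protein genes.

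At the same threshold the authors' deposited table has 367 genes higher and 688 lower with extract by adjusted p. Of these, 884 were also called here, 171 were called in the table alone, and 14 were called here alone. Both sets of calls come from the same 6 libraries, and the genes had been selected on them, so shared calls are no independent support. The sign was the same in 1099 of 1099 genes, as it must be with size factors taken from those fold changes. The 11 genes that the table marks as significant were all lower with extract.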

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

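The scale implied by the TPM values and the adjustment over the listed genes alone were chosen after seeing the data. The count of 580 lower genes was 87 with TMM, 86 with DESeq2 size factors and 126 with plain sums over the listed genes, and 197 on the TPM scale. Those scales raise the extract libraries relative to vehicle, and the calls of higher genes stayed within 1.5 times of 318. Of 1099 genes 53 changed sign with DESeq2 size factors over the listed genes, 25 with TMM, 6 with sums and 0 on the TPM scale, by the same shift. The 53 include ANLN, ECT2 (0.0016) and NFE2L2 (0.012). Leaving out each library in turn gave 50 to 287 higher and 128 to 571 lower genes, with fewer samples per fit. The replicate number as a block gave 86 higher and 222 lower genes. Deviations of libraries with the same number correlated at -0.23, -0.010 and -0.032, and no library correlated best with its own number. These values give no sign that the numbers pair the libraries, but do not settle it. The 5 called lists were 0 with an estimated correlation and 13 with fry, and the 27 called terms were 0 with an estimated correlation. fry does not set a list against the other listed genes. As all members had been selected on small p-values, its 13 calls add no support. DESeq2 gave 371 higher and 689 lower genes, and limma-voom 317 and 590. Like edgeR, both estimated the spread from the selected genes alone. The median log10 ratio of p-values to the deposited ones was 0.60 for edgeR and -0.42 for DESeq2. Adjustment over the listed genes alone gave 387 and 712, which is every listed gene and follows largely from their selection. The 2 filters on low counts removed no gene and test nothing. The table stops at a deposited p-value of 0.00535, so smaller changes were not analysed here.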

Other observations

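Which families to count by symbol, and the tests on cell identity, library scale and regrouping below, were chosen after the values had been seen. All 7 listed keratin genes were lower and passed the edgeR test, with a median log2 fold change of -0.95 and a range from -1.39 (KRT13) to -0.28 (KRT17). The others were KRT81, KRT75, KRT6A, KRT80 and KRT6B, most of them keratins of stratified or hair epithelium. All 8 listed S100 genes were lower and 7 passed, with S100A2 lowest at 1.99-fold and S100A11 at -0.19 on the log2 scale. By Fisher's exact test against the direction of the other listed genes, adjusted over 18 families, neither family stood apart (adjusted p = 0.234 and 0.169), since most listed genes were lower. The annotation terms for cornification (9 of 10 lower, camera adjusted p = 0.157) and intermediate filament (9 of 10 lower, camera adjusted p = 0.318) were not called either. None of the keratin and S100 genes could change sign under the 4 other scales, which move genes by at most 0.17, less than any of these decreases. On each of the 4 scales 4 of each family passed.

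By symbol, 52 cytosolic ribosomal protein genes were in the table and all 52 were lower (Fisher adjusted p = 2.39e-09), although 4 turned higher with TMM and 9 with DESeq2 size factors over the listed genes. The 43 that passed fell to 20 on the TPM scale, 11 with sums, 7 with TMM and 8 with DESeq2 size factors over the listed genes, and the KEGG ribosome term was at a camera adjusted p of 0.907 with an estimated correlation. All 14 listed subunits of the respiratory chain and ATP synthase were lower (median -0.30, Fisher adjusted p = 0.0296), among them ATP5F1E at -0.37. None could change sign under the other scales, which move genes by less than the smallest of these decreases. The 11 that passed fell to 5 on the TPM scale, 1 with sums and 0 with TMM or DESeq2 size factors over the listed genes. The list of oxidative phosphorylation genes fixed beforehand had 3 of 37 members listed, against 3.60 expected (hypergeometric adjusted p = 0.832), and the KEGG term for oxidative phosphorylation (14 of 14 lower) was not called by camera (adjusted p = 0.0891, or 0.907 as adjusted p with an estimated correlation). All 9 listed mitochondrial ribosomal protein genes were lower (median -0.27, Fisher adjusted p = 0.140), and none of them passed on any other scale. All 9 listed proteasome subunits were lower too (Fisher adjusted p = 0.140), with 3 changing sign with DESeq2 size factors over the listed genes and at most 1 passing on any other scale.

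A candidate explanation for MTAP and gastrointestinal genes in libraries labelled A549 is that the libraries come from another cell line. MTAP, which A549 lacks, never fell below 48.9 TPM in the 6 libraries, as this explanation needs. Admixture of another line in A549 cultures could also bring these genes. Vimentin, abundant in A549, reached at most 12.2 TPM against a median of at least 51.3 TPM over the listed genes, which argues against a large A549 share. This rests on an assumed profile of A549, so admixture stays open. With extract the 3 listed genes known to be abundant in A549 and vimentin were higher and the 6 gastrointestinal ones lower. A change in the mixture could move genes in these directions, as could regulation of these genes, of which NQO1 and SLC7A11 are also NRF2 targets. If A549 lacks MTAP, a change in the mixture alone would lower no gene by more than MTAP, at -0.19 (SE 0.04). TSPAN8 was also at -0.19, but EPS8L3 was at -0.35 (SE 0.07), VIL1 at -0.42 (SE 0.04), CDH17 at -0.43 (SE 0.07), REG4 at -0.78 (SE 0.17) and TFF1 at -0.83 (SE 0.16). Apart from TSPAN8, these values argue against a change in the mixture as the only cause of the gastrointestinal decreases. The design offers no group that tests a biological explanation, and which line was used cannot be settled from these genes.

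The opposite shifts of interferon and lysosome lists (29 genes higher) and of ribosome lists (46 genes lower) could come from gene length, GC content or the library scale. Listed genes matched to the ribosome lists were lower in 79.3% of cases by length and in 67.0% by GC content, both below 92.3%, the lower 95% bound of the members' own share of 100%. Genes matched to the interferon and lysosome lists were higher in 36.9% by length and in 33.1% by GC content, against a bound of 88.1%. Matched genes thus shared the direction less often than the members did. The bounds take members as independent, while the estimated correlation within the 4 lists ran from 0.30 to 0.46. They are therefore too high, and cannot decide whether either property accounts for a whole shift. Of all listed genes 712 of 1099 were lower, a share that genes matched on length to the ribosome lists exceed. By symbol 52 cytosolic ribosomal protein genes were in the table, against 26 on the list, and those off the list could serve as matched genes. Whether short length itself goes with part of that decrease therefore cannot be told. The library scale stays open for both. It moves all genes of a library alike, so it leaves the distance between the lists as it is and moves only the point of no change. All 4 other scales raise the extract libraries, which fixes that 100% of interferon and lysosome members stayed higher. For the ribosome lists at least 89.1% stayed lower, but the 5 of 46 that turned higher did so with DESeq2 size factors over the listed genes, which centre on genes selected as changed. The TPM scale moves genes by 0.088, less than the smallest decrease of any listed gene (0.115), so no sign could change there. That scale is a single factor per library. In the deposited TPM values themselves 8 of 1099 genes had the other sign, among them RPS6, with a mean of 2114 TPM in vehicle and 2164 in extract. No biological explanation was tested.

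The balance of genes called lower and higher may depend on the library scale. On the scale implied by the TPM values 34.7% of calls were lower, against 64.6% with the size factors of the authors' fold changes, so the balance of calls turned. Listed genes were still 712 lower and 387 higher there, with 0 signs changed, so only crossings of the threshold moved. The shift fixes the direction of this move but not its size, and genes that would pass on that scale alone are outside the table and were not analysed here. The TPM scale divides by all transcripts, whose total moves with abundant ribosomal and ferritin genes, and these data do not tell which scale is closer to RNA per cell. Of the 10 splits of the 6 libraries into groups of 3, only 1, the real one, gave as many called genes, with 898 against at most 0 in the others. With 10 splits a share under 0.05 cannot be reached, and the genes had been selected on the real split.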
